A study of Caenorhabditis elegans with 4 samples.

How the data were processed

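The series measured DNA bound by PAX-1::GFP in C. elegans embryos of mixed sex by ChIP-seq. Per the labels' protocols, worms were grown at 20 °C, crosslinked with 2% formaldehyde and sonicated, part of the lysate was kept as Input, and the rest was incubated with anti-GFP antibodies. The 4 samples were grouped by their titles into ChIP (n = 2, replicates 1 and 2) and Input (n = 2, replicates 1 and 2).

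The deposited data are 3 lists of regions in GFF version 3 format: one for each ChIP replicate and one combined list. Coordinates are on WormBase WS220, per the file headers, and are given 1-based. The source column of each list names SPP, a ChIP-seq peak caller, and IDR, a procedure that keeps regions ranked alike in replicates (spp_via_IDR), per the files. The aligner, the tool versions, the thresholds, the use of the Input libraries and the way the replicates were combined are not given in the sources used here. Each region carries a score that the authors deposited in column 6, whose scale is not stated. The score has a ceiling in each list: 435 combined regions (47.4%) shared the highest value of 2.95, as did 1111 regions of replicate 1 at 3.35 and 119 regions of replicate 2 at 2.37. Regions are also numbered, and number 1 was taken as the highest because the first numbers of each list carry its highest score. Over a whole list the numbers rise as the score falls (Spearman correlation -0.931 in the combined list, -1.00 in replicate 1 and -0.998 in replicate 2), but below the ceiling the score falls in steps. Inside the first step it rises with the number in each list. Over all neighbouring numbers below the ceiling it rises for 94.6% in the combined list, 50.9% in replicate 1 and 50.5% in replicate 2. In the combined list it rises from 2.47 at number 436 to 2.61 at number 600, so number and score order those regions oppositely. Because the score is capped, regions were ranked by their number, within a list only, and a higher region means one with a lower number. The upper 50% of the combined list ends at number 459, inside that step, and 435 of its 459 regions are also in the upper 50% by score. In replicate 1 the numbers end at 30000, a round total. Whether the list was cut there is not stated, and a cut would limit how many weak regions can be shared.

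From the lists, regions on the 6 nuclear chromosomes were compared. 23 mitochondrial regions of replicate 1 and 21 of replicate 2 were left out of these comparisons. Chromosome lengths were taken as the last base listed in any of the 3 lists, 100.2 Mb in total. Regions counted as shared when they overlapped by at least 1 bp. The chance level came from 10000 circular shifts of one list, with a random offset for each chromosome, which keeps the spacing of its regions. This is a permutation test of positions, and its p-value is the one-sided share of shifts with as much overlap. Shares carry 95% Wilson intervals. Ranks were compared by Spearman correlation over mutual best matches, with 2000 bootstrap draws of regions. Chromosome shares were compared with the share of length by two-sided exact binomial tests with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of protein-coding genes per chromosome (19971 in total) came from a RefSeq gene table of assembly WBcel235, of which no coordinates were used. The functions were tested on simulated lists of 900 regions. With 300 planted shared regions 302 overlaps were counted, and 299 of the planted pairs were matched. Planted changes on chromosomes III and V were both called. Of 40 pairs of independent lists 0 reached a permutation p of 0.05, and of 40 uniform lists 2 had any chromosome called. The simulated regions were placed evenly and independently, so these rates need not hold for clustered regions or for the longer replicate lists.

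The tests of the Results, their alternatives and the rule for the regions named were fixed before the data were examined, with the exceptions given here and in the closing observations. By that rule the 10 highest combined regions are named by position, because no annotation of WS220 was at hand. All other regions and stretches named were picked after their values were seen. The alternatives fixed in advance were stricter overlaps (at least 50% of both regions, or midpoints within 200 bp), the upper 50% of a list, equal numbers of the highest regions, expectation by gene number, and the 917 highest regions of each replicate alone. Counting regions within 5000 bp once, and taking the expected shares from replicate regions outside the combined list, were chosen after seeing the data, as were matching by midpoints within 200 bp inside the combined list, ranking by score, and the comparison of the upper 50% with random draws. The 4 planned results that need gene positions or sequence of WS220 were not run. These are regions near gene starts, enrichment of 20 gene lists, the paired-domain motif, and the pax-1 locus itself. The strain carries added pax-1 copies, and a region at that locus was not looked for. The gene table covers another build, and coordinates were not converted. Versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.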

Results

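PAX-1 is a paired-box transcription factor of the nematode Caenorhabditis elegans, and paired-box proteins bind DNA through a conserved domain. Its binding sites were mapped in embryos by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA crosslinked to a protein is recovered with an antibody and sequenced. The embryos came from a strain, OP117, that carries a transgene for PAX-1 fused to green fluorescent protein (GFP), and an anti-GFP antibody recovered the fusion protein. The series holds 4 samples, 2 ChIP samples and 2 Input samples of total chromatin DNA. Each ChIP sample has 1 list of called regions, and a combined list covers both. The Input samples have no list used here, so no background regions could be counted in them. Replicate 1 listed 30000 regions and replicate 2 listed 19190. The combined list held 917 regions that covered 439 kb, or 0.438% of the listed extent of the nuclear chromosomes. Read depth is unknown, because the lists give regions and scores without read counts. With 1 list per replicate there is no spread between replicates for most values, and the intervals given for shares cover the counting of regions only. Whether the replicates came from separate worm cultures is not stated.

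The study set out to locate the sites that PAX-1 occupies in the embryo. The highest combined region lay on chromosome X at 16929522 to 16929937 (WormBase WS220) and was also region number 1 in both replicate lists. The region ranked 2 lay on X at 3306885 to 3307208 and was number 2 in replicate 1 and number 3 in replicate 2. The region ranked 3 lay on X at 11605837 to 11606128 and was number 42 in replicate 1 and number 2 in replicate 2. The regions ranked 4 and 10 lay on chromosome III, at 9353806 to 9354037 and at 9053930 to 9054169. The regions ranked 5 and 9 lay on chromosome I, at 12966818 to 12967049 and at 14759392 to 14759611. On chromosome V, the regions ranked 6 and 7 lay at 11083613 to 11083797 and at 10897227 to 10897444. The region ranked 8 lay on X at 11093859 to 11094354 and was number 4 in replicate 1 but number 131 in replicate 2. The other 6 of these 10 regions were between number 5 and 56 in replicate 1 and between number 8 and 18 in replicate 2. All 10 carry the highest score of the combined list, 2.95, so their order rests on the region numbers alone. In all 10, the midpoints of the highest overlapping replicate regions lay within 38 bp of each other. Genes at these positions were not analysed here, because no annotation of the WS220 build was used.

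**Figure D1:**
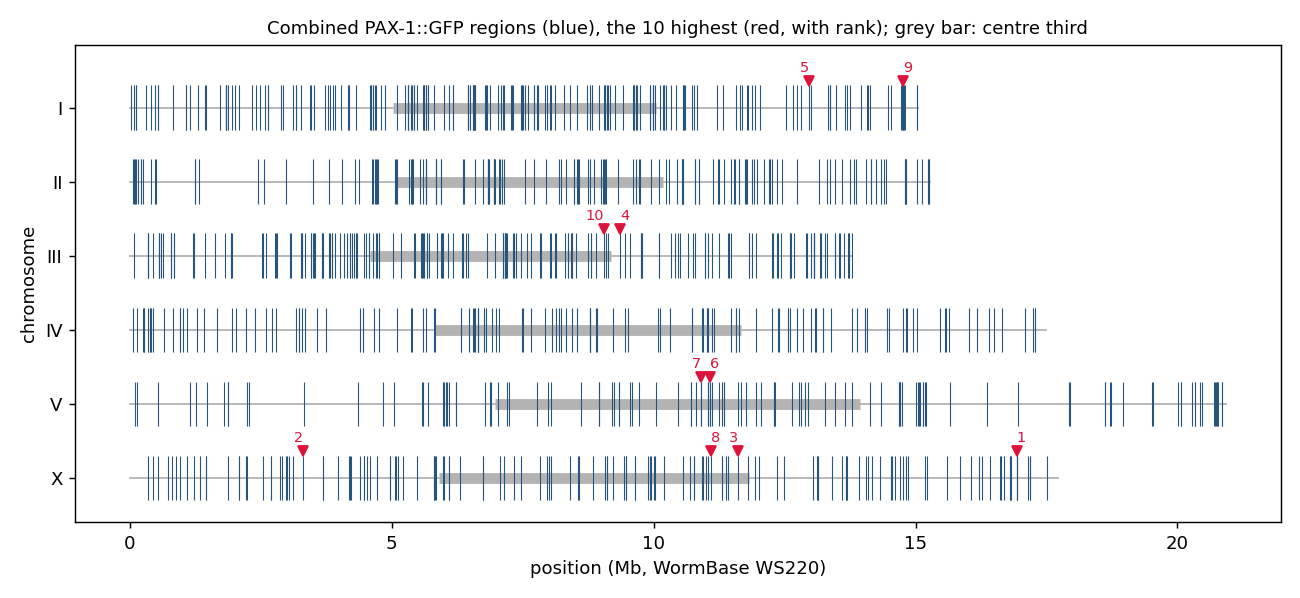
Positions of the 917 combined regions (blue ticks) along the 6 nuclear chromosomes in Mb (WormBase WS220), with the 10 highest marked by red triangles and their rank. The thick grey bar is the middle of 3 equal parts of each chromosome. 4 of the 10 highest regions lie on X.

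The replicate comparison asked how far both libraries listed the same places. Among the nuclear regions of replicate 2, 53.1% (10180 of 19169, 95% Wilson interval 52.4% to 53.8%) overlapped a region of replicate 1 by at least 1 bp. Circular shifts of the list along each chromosome gave 24.9%, so the overlap was 2.13 times that of shifted lists (one-sided circular-shift permutation test, p = 0.0001, the smallest that 10000 shifts can give). Among the nuclear regions of replicate 1, 34.02% (10198 of 29977, interval 33.5% to 34.6%) overlapped replicate 2, against 16% in shifted lists (permutation p = 0.0001). The rate of sharing was highest among high-ranked regions and fell with rank, although by count many shared regions ranked low. In replicate 1, 2789 shared regions had numbers 19191 to 30000, and in replicate 2, 4131 had numbers 10001 to 19190. Of the nuclear regions numbered 1 to 100, 95.9% of replicate 1 (94 of 98) and 100.0% of replicate 2 (91 of 91) had a partner in the other list. In replicate 1 the share was 51.5% for numbers 1001 to 5000 and 25.8% for numbers 19191 to 30000. In replicate 2 it was 63.5% for numbers 1001 to 5000 and 44.96% for numbers 10001 to 19190. When only the 917 highest nuclear regions of each list were compared, 42.1% of those of replicate 2 lay on one of replicate 1, against 0.886% in shifted lists (permutation p = 0.0001).

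**Figure D2:**
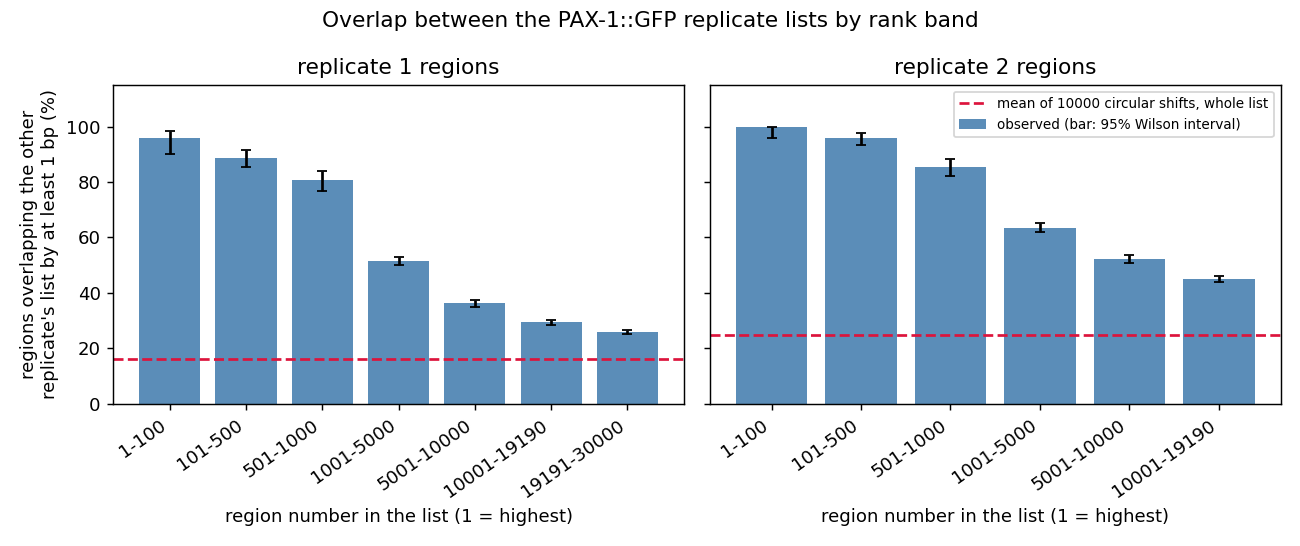
Percentage of nuclear regions in each band of region numbers that overlapped the other replicate's list by at least 1 bp, for replicate 1 (left) and replicate 2 (right). Error bars are 95% Wilson intervals and the dashed line is the mean of 10000 circular shifts of the whole list (16% and 24.9%). In both panels the share falls from the highest band to the lowest and stays above the line.

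Strong regions present in a single replicate were more numerous in replicate 1. Of its 917 highest nuclear regions, 125 (13.6%, interval 11.6% to 16%) overlapped no region of replicate 2, and the highest of these was number 50. Of the 917 highest in replicate 2, 80 (8.72%, interval 7.07% to 10.7%) overlapped none in replicate 1, and the highest was number 156. The lists compared against differ in length, 19169 against 29977 nuclear regions, and a longer list gives more overlaps by chance.

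Nearly all combined regions had a counterpart in each replicate. In total 891 of 917 (97.2%, interval 95.9% to 98.1%) overlapped regions of both lists, against 8.20% for shifted positions (permutation p = 0.0001 in 10000 shifts). A further 25 overlapped replicate 1 alone, 1 overlapped replicate 2 alone, and none overlapped neither list. The highest region without replicate 2 support lay on chromosome I at 5105960 to 5106455 and was number 50 in replicate 1. The single region without replicate 1 support lay on chromosome II at 11238808 to 11239303 and was number 1258 in replicate 2. These 2 regions were picked after their values were seen. The combined list drew more on the top of replicate 1: 75.1% of combined regions lay on its 917 highest nuclear regions, and 56.9% lay on the 917 highest of replicate 2. The top of both lists held 367 combined regions (40.02%), and 73 were in the top of neither. The median region number of a combined region was 508 in replicate 1 (quartiles 232 and 929) and 686 in replicate 2 (quartiles 247 and 1911). Numbers beyond 5000 occurred for 10 combined regions in replicate 1 and for 94 in replicate 2. The combined list was made from these libraries, so its overlap with them is not independent evidence of binding.

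The distance between replicate regions at the same site was measured by midpoints. Over the 891 combined regions found in both lists, the midpoints of the best replicate regions differed by a median of 47 bp (interquartile range 85 bp). Both had to overlap the same combined region, which limits the distance, and no chance value was computed. Among the 100 highest combined regions the median was 25.5 bp, and among the other 791 it was 51 bp. The regions themselves were mostly of 1 fixed width per list, 410 bp in replicate 1, 520 bp in replicate 2 and 496 bp in the combined list.

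The order of the shared regions was compared by their numbers. Across 8599 regions matched one to one between the nuclear lists, the Spearman correlation of region numbers was 0.337 (95% bootstrap interval 0.316 to 0.357). Across the 870 matched regions inside the combined list it was 0.0712 (interval -0.00068 to 0.139), an interval that includes 0. Matching by midpoints within 200 bp instead, a setting added after seeing the data, gave 0.134 (interval 0.0625 to 0.205) across 859 regions inside that list, and that interval excludes 0. Ranked by score, also added later, the same 870 gave -0.142 (interval -0.197 to -0.0847), where 703 of them share the highest score of replicate 1 and so have no order there, and all 8599 gave 0.334. Across the 7729 matched regions outside the combined list it was 0.164 (interval 0.140 to 0.185). These correlations are across regions, which are not independent replicates, and no p-value was attached to them.

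**Figure D3:**
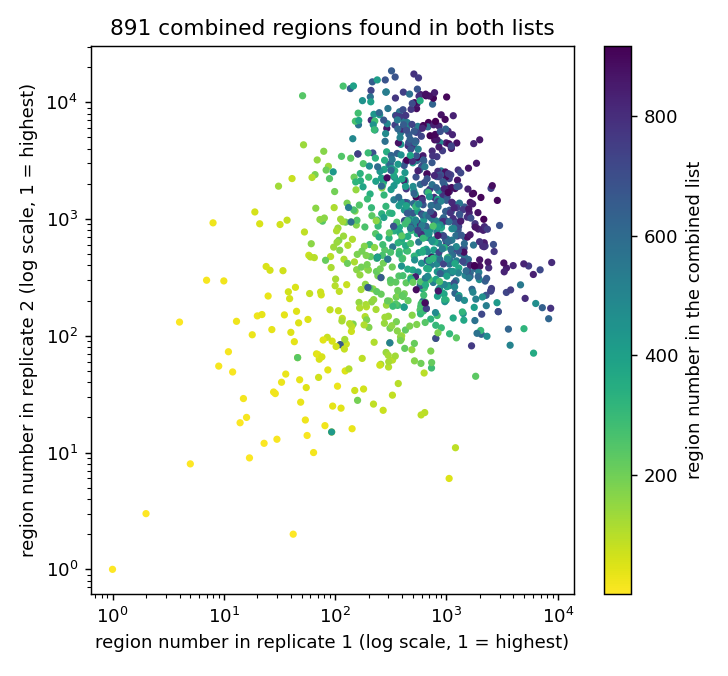
Region number in replicate 1 (horizontal, log scale) against region number in replicate 2 (vertical, log scale) for the 891 combined regions found in both lists, coloured by their number in the combined list. Number 1 is the highest. The highest combined regions sit at low numbers in both lists, and the later ones spread over a wide range in replicate 2.

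Combined regions were unevenly spread over the chromosomes. Chromosome I held 194 of 917 regions (21.2%, interval 18.6% to 23.9%) and chromosome III held 178 (19.4%, interval 16.98% to 22.1%), against 15.02% and 13.7% expected by length. These were 1.41-fold above the expected share on each (exact binomial test, two-sided, Benjamini-Hochberg over 6 chromosomes, adjusted p = 2.1e-06 for I and 3.9e-06 for III). The exact tests here and below take regions as independent, but combined regions lay close together more often than evenly placed ones (closing observations). Their p-values may therefore be too small. Chromosome V held 120 (13.1%, interval 11.1% to 15.4%) against 20.9% expected by length, or 0.627-fold (exact test, adjusted p = 7.2e-09). Chromosome IV held 135 (14.7%) against 17.4%, or 0.844-fold, with an adjusted p of 0.044 in the exact test. This call did not hold under any alternative fixed in advance, with an adjusted p of 0.20 against gene number, 0.50 in the upper 50% of the list, 0.068 without replicate 2 and 0.21 without replicate 1 (exact tests). The share stayed below the expected one in each of them, from 0.856-fold without replicate 2 to 0.924-fold in the upper 50%. Chromosomes II and X each held 145 regions (15.8%), which differed from the 15.2% and 17.7% expected by length with adjusted p = 0.61 and 0.18 in the exact test. By the number of protein-coding genes, X was expected to hold 13.7%, so the direction for X depends on the reference, and neither difference passed the test. It also depends on the replicate: the 917 highest regions of replicate 2 alone had 14.2% on X (0.802-fold by length, exact test, adjusted p = 0.0073), and those of replicate 1 alone had 18.1% (1.02-fold, adjusted p = 0.87). In the upper 50% of the combined list chromosome I held 18.7% (adjusted p = 0.062), chromosome III 20.3% (adjusted p = 0.00041) and chromosome V 13.1% (adjusted p = 0.00012), by the same exact test.

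**Figure D4:**
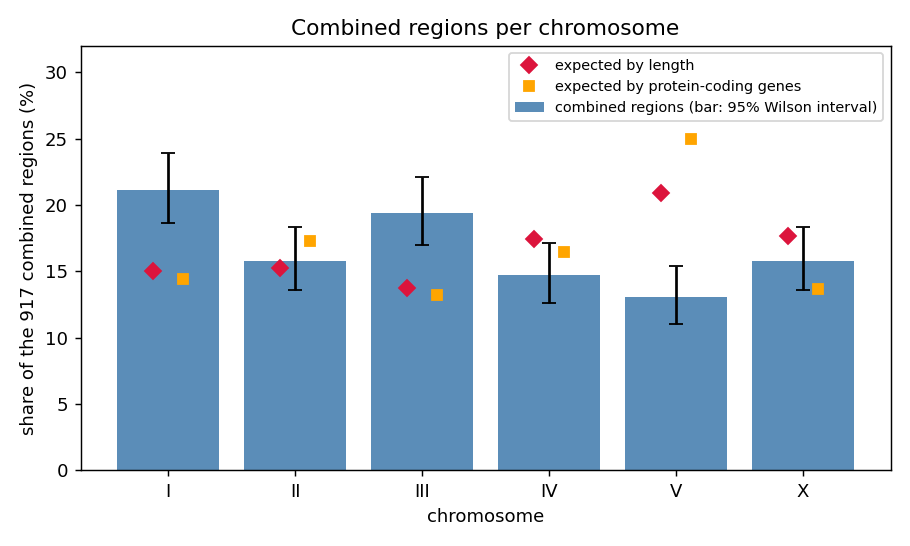
Share of the 917 combined regions on each nuclear chromosome in percent (bars, with 95% Wilson intervals), beside the share expected by chromosome length (diamonds) and by the number of protein-coding genes (squares). The intervals of chromosomes I and III lie above both expectations and that of chromosome V lies below both.

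Nematode autosomes are commonly divided into a gene-dense centre and repeat-rich arms, and the position along each chromosome was compared with an even spread. The middle of 3 equal parts held 354 of 917 combined regions (38.6%, interval 35.5% to 41.8%) against 33.3% expected by length (exact binomial test, two-sided, Benjamini-Hochberg over 7 tests, adjusted p = 0.0060). On chromosome I it held 86 of 194 (44.3%, exact test, adjusted p = 0.0060). The part held 58 of 145 regions on II, and the shares were 34.8% on III, 37.04% on IV, 40.8% on V and 33.8% on X, with adjusted p between 0.17 and 0.93. In the upper 50% of the combined list the middle part held 35.5% over all chromosomes and 40.7% on chromosome I, and neither passed the test. Among the 917 highest regions of replicate 1 alone it held 37.8% and 44.7% (exact tests, adjusted p = 0.014 and 0.013). Among those of replicate 2 alone it held 38.5% and 41.3% (exact tests, adjusted p = 0.0039 and 0.041).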

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

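All tests in this part were chosen after the result was seen. Replicate 1 listed 23 regions on the mitochondrial genome and replicate 2 listed 21, while the combined list held none. They stood out because they lie outside the measurement compared above. Several ranked very high. In replicate 1 the region at 13036 to 13296 was number 3, 2 of the 23 were among the 100 highest and 14 among the 1000 highest. In replicate 2 the region at 6505 to 7024 was number 4, 9 of the 21 were among the 100 highest and 16 among the 1000 highest. The regions covered 58.3% of the 13812 bp listed extent in replicate 1 and 62.4% in replicate 2. Of 7254 nuclear windows of that length, 0 were covered as much in either replicate, with maxima of 45.1% and 39.7%. Even high read depth would give such coverage, a prediction written after the data were seen. The base pairs listed in both replicates came to 5104, against a mean of 5029 over 13811 rotations of one list along the genome, and 40.9% of the rotations gave as many. One strong pair did coincide: the region at 13054 to 13256 was number 5 in replicate 2. Over the whole lists, the rotations do not decide whether the replicates list the same mitochondrial positions beyond chance, since both lists cover much of the extent. Whether high read depth over mitochondrial DNA gave these regions stays open, since the covered share follows from their number and width and no Input list was used here, and no biological explanation was tested.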

How the results depend on the processing

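No paired analysis was possible because no model was fitted across samples and the Input samples have no list used here. Of 138 alternative values for 30 results, 101 kept their direction and their side of the threshold or stayed within the interval. The overlaps of the replicate lists, the support of the combined regions, and the chromosome III and V shares kept both under every alternative run. For the support this is no independent check, because the combined list was made from the same libraries. It fell from 97.2% to 40.02% when only the 917 highest nuclear regions of each replicate were used. The upper 50% of the lists holds 459, 15000 and 9595 regions by construction. Rank agreement was 0.363 with midpoints within 200 bp and 0.0712 inside the combined list, where both settings together gave 0.134 and ranking by score turned it to -0.142. With the upper 50% of the combined list chromosome I (18.7%), chromosome IV (16.1%), the middle part overall (35.5%) and that of I (40.7%) no longer passed the test, and the middle of III turned to 32.3%. By score these were 18.7%, 15.7%, 36.2%, 45.3% and 30.1%. Random draws of 459 combined regions passed in 96.1% of 10000 for I, 17.65% for IV, 37.8% for the middle and 33.1% for that of I. Fewer regions thus ended the last 3 calls in most draws, but that of I in few. I held 23.6% of the other regions (Fisher's exact p = 0.076), and the middle part overall held 41.7% of them (Fisher's exact p = 0.058). For IV (13.3%) and the middle of I (47.2%) Fisher's exact p was 0.26 and 0.39. None of these differences passed the test. The draws therefore do not tell whether list size alone ended the call of the middle part overall. Chromosome IV passed against replicate regions outside the list (0.820-fold and 0.801-fold) and failed against gene number (14.7%), with neighbours counted once (14.7%) and with 1 replicate alone (14.9% to 15.8%). Against gene number, II (15.8%, 0.916-fold) and X (15.8%, 1.16-fold) turned direction without passing the test. With 1 replicate alone, X held 14.2% to 18.1%, and without replicate 1 its deficit passed the test (14.2%). The middle part then held 34.8% to 42.9% on II and 42.3% to 48.3% on V, both past the threshold without replicate 1, and 28.5% to 29.5% on X, where it turned direction, as it did with neighbours counted once (32.6%). Beyond the draws the cause was not tested. Of the 10 named regions, 7 were shared with only 1 replicate at 50% of both regions. Among the 20 highest regions the median width was 174.5 bp in replicate 1 and 520 bp in replicate 2, but the reason was not tested. The gene-start, gene-list, motif and pax-1 results and their alternatives were not run. Read depth is unknown, so its effect on weak regions could not be bounded.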

Other observations

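The tests of neighbouring regions were chosen after the data were seen, as were the stretches and the site named in this part. Combined regions lay close to each other more often than evenly placed ones. There were 83 neighbouring pairs with midpoints 500 to 5000 bp apart, against a mean of 40.1 (range of 95% of draws 29 to 52) when the same numbers were placed at random within each part of each chromosome, a 2.07-fold excess (one-sided permutation test, p = 0.0001, the smallest that 10000 draws can give). Draws from the 8599 regions matched between the replicates gave a mean of 53.7 (41 to 68), so the excess over those was 1.55-fold (permutation p = 0.0001). The densest 250 kb stretch was on chromosome I from 5250001 to 5500000, with 9 combined regions, against a mean of 2.27 per stretch, and the next stretch on I from 5500001 to 5750000 held 7. Stretches with 8 regions lay on II from 6750001 to 7000000, on IV from 250001 to 500000 and on V from 15000001 to 15250000. The 8 on II include overlapping regions, such as 6831690 to 6832185 and 6831894 to 6832389, so they mark fewer separate sites. Of 404 stretches 69 held none.

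Chromosome X held 4 of the 10 highest combined regions and 141 of the other 907 (15.5%), a difference that did not pass a two-sided Fisher's exact test (p = 0.058) and was looked at after the ranks were seen. Among the 100 highest, 17 were on X (Fisher's exact test, p = 0.77). One nuclear site stood in the 100 highest of both replicates and not in the combined list: on chromosome II at 4999129 to 4999538, number 88 in replicate 1, and at 4999045 to 4999564, number 79 in replicate 2. The nearest combined region was 56022 bp away. The other 37 of 38 such pairs were in the combined list. Among the 20 highest combined regions 17 were narrower than the usual 496 bp, as were 18 of the other 897.

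The tests of the chromosome pattern were chosen after the counts were seen, except the one by gene number, which was planned as an alternative, and those of rank agreement by number were written before their results. Ranking by score was added later. Chromosomes I and III held more combined regions than their length predicts, and V fewer. Gene number does not account for it, since against gene shares chromosome III stayed at 1.47-fold, I at 1.47-fold and V at 0.523-fold (exact binomial tests, adjusted p = 3.3e-07, 9.9e-08 and 3.8e-18). Against replicate 1 regions outside the combined list, III was at 1.25-fold, I at 1.29-fold and V at 0.760-fold (exact tests, adjusted p = 0.0033, 0.0011 and 0.0022). With replicate 2 regions outside it, III was at 1.21-fold, I at 1.24-fold and V at 0.770-fold (exact tests, adjusted p = 0.010, 0.0040 and 0.0040). The spread of those regions may be part of the pattern, but it did not account for all of it. Most of them rank low, so whether a bias in listing high-ranked regions gave the rest cannot be told. With neighbours within 5000 bp counted once, III was at 1.38-fold, I at 1.397-fold and V at 0.629-fold. A hypothesis that remains is that PAX-1 sites follow features that differ between chromosomes, which these lists cannot test without WS220 gene positions, and mappability and open chromatin stay open too.

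Rank agreement between replicates was 0.337 over all matched regions and 0.0712 inside the combined list, and -0.142 there when ranked by score (interval -0.197 to -0.0847), where 703 of 870 regions share the highest score of replicate 1. By number, pairs inside it with midpoints within 200 bp gave 0.134 (95% bootstrap interval 0.0625 to 0.205), below the interval over all matched regions, so wrong matches are not the whole reason. Choosing 870 matched regions by the sum of their ranks gave 0.158 (interval 0.0905 to 0.225), which overlaps the interval inside the combined list (up to 0.139). By the rule written before the result, a value above 0.139 counted against selection on joint rank as the cause, and 0.158 lies above it. The intervals overlap, however, so that rule does not settle the question. The combined list also holds 94 regions beyond number 5000 in replicate 2, up to number 18561. A choice by the sum of ranks therefore need not mimic how that list was made. Selection on joint rank may account for part of the drop. Whether it accounts for all of it cannot be told apart from a real difference in the order of strong sites.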
